A study of Arabidopsis thaliana with 8 samples.

How the data were processed

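Total RNA from leaves of Arabidopsis thaliana, accession Col-0, was profiled on 8 one-colour Affymetrix arrays, 4 labelled wild type and 4 labelled fbn5-1, a T-DNA insertion mutant of FBN5. Per the labels' protocols, plants were 3 weeks old, were kept at 25 °C and 60% humidity with 16 h of light and 8 h of dark, and received no treatment. The medium was 0.5x MS with 1% sucrose. RNA was extracted with Trizol, and biotin-labelled cRNA was made from 200 ng of total RNA. The labels number 4 replicates per genotype without saying whether these came from separate plants or cultures, so every p-value measures the spread between these samples, which may be technical.

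The deposited values are on a log2 scale, one value per probe set and array, with 2 decimals. The log base is not stated; log2 was taken from the range of the values, which natural or base-10 logs of a scanner could not give. The submitters' processing notes name MAS5; background correction, summarization, log transform and scaling are otherwise not given in the sources used here. A series table of 38408 probe sets and a series matrix of 28583 probe sets were compared, and their shared probe sets were identical (largest difference 0). The matrix was used, because its probe sets could be named. The 9825 found in the table alone entered 1 alternative and a comparison of array medians. Array medians over the matrix lay between 3.42 and 3.49, so the deposited scaling was kept. The number of arrays limits the precision of each value.

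Of the 28583 probe sets, 16746 are listed with 1 gene symbol, 758 with several and 11079 with none; probe sets with several symbols or none were tested but not named. Symbols were updated by gene number through a RefSeq gene table of assembly TAIR10.1, in which 16601 of the 16746 were found. That table was used for names and gene order alone, and no coordinates are given because no genome build is named for the array. The values of 404 probe sets repeat those of another on all 8 arrays. Detection calls and labelled control probe sets were not used here, so the planned share of Present calls and the 3 prime to 5 prime ratios were not computed. In their place, the planned fallback filter was applied: a probe set was tested if its mean over the 8 arrays lay above the 40th percentile (log2 2.79), which left 17147, of which 9066 name 1 gene.

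Groups were compared with limma (lmFit, eBayes with an intensity trend; limma 3.58.1, R 4.3.3), two-sided, as arrays labelled fbn5-1 minus arrays labelled wild type. Adjusted p-values follow Benjamini and Hochberg over the 17147 probe sets, and a probe set was called at an adjusted p under 0.05. Values are given with their standard error (SE). Tests of single quantities per array were exact permutation tests, two-sided, for which 4 against 4 arrays allow no p below 0.0286. In simulated data with the real means and spreads of the 17147 probe sets, and 100 changed at each size, limma recovered 73% of changes of 1 and 26% of changes of 0.5 on the log2 scale. It made 7 false calls among 106, and 0 calls where nothing was changed. The simulated noise was independent between probe sets, no array stood apart, and few probe sets were changed. These rates may therefore not carry over to the real data.

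Gene lists were written before the data were examined: 28 by function or cell type, and the plastid and mitochondrial genomes. Only 67 of the 465 entries of the first 28 had a probe set of their own, so 10 of these 30 lists had the 3 tested members needed. Another 30 lists were drawn from the symbols present on the array once these were known and before any gene was compared between groups, though after the correlations between arrays had been seen; 29 of them had enough tested members, which gave 39 in all. A gene was represented by its brightest probe set over the 8 arrays. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. Fry asks whether a list moves one way on balance, without comparing it with other genes.

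Named genes followed a rule fixed beforehand. It took the fibrillins and the 10 highest and 10 lowest changes among called probe sets that name 1 gene. For these changes, the 4 values in one group all had to lie above the 4 of the other. The rule also took up to 4 called members per fixed list, by size of change. In added lists, members were picked likewise, but only from lists called in these data, so that choice was not fixed beforehand. Genes named in neither way were chosen after their values were seen. What a gene encodes is stated as background and was not read from the files. Alternatives covered 3 other scalings, 16 added to the linear signal, no filter and a 60th percentile filter, eBayes without trend and with a robust trend, the whole series table, the replicate number as a block, array weights and leaving out each array. In the alternatives without trend and with a robust trend, lists were tested with cameraPR on the moderated statistics, so a changed list call there may come from that test. Alternatives chosen after seeing the data were counting identical probe sets once and testing the added lists with the fixed ones. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were read with pandas 2.3.3.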

Results

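Leaf RNA of the fbn5-1 T-DNA insertion line was compared with that of wild type on 4 arrays each. FBN5 (AT5G09820) encodes a plastid fibrillin, a family of lipid-associated proteins of plastoglobules, thylakoids and stroma, and is linked to plastoquinone synthesis. The comparison asks which transcripts differ in leaves when FBN5 is disrupted. Because the signal of the targeted gene went against its label, as given next, arrays are called by their label throughout, and every direction rests on those labels.

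FBN5 itself was not lower in the arrays labelled fbn5-1. Its log2 signal was 3.54, 3.35, 3.43 and 5.15 on the arrays labelled wild type 1 to 4, and 4.71, 4.52, 4.76 and 4.58 on those labelled fbn5-1 (means 3.87 ± 0.86 and 4.64 ± 0.11, SD, n = 4). The difference of 0.78 (SE 0.36) did not pass the test (adjusted p = 0.173; exact permutation p = 0.143). Without wild type array 4 it was 1.203 (SE 0.11, adjusted p = 0.000534), and with 16 added to the linear signal on all 8 arrays 0.375. Where the probe set lies relative to the insertion is not known, so its level may check nothing about the labels. The plot of FBN5, FBN8 and AT5G33370 per array shows these values.

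**Figure D1:**
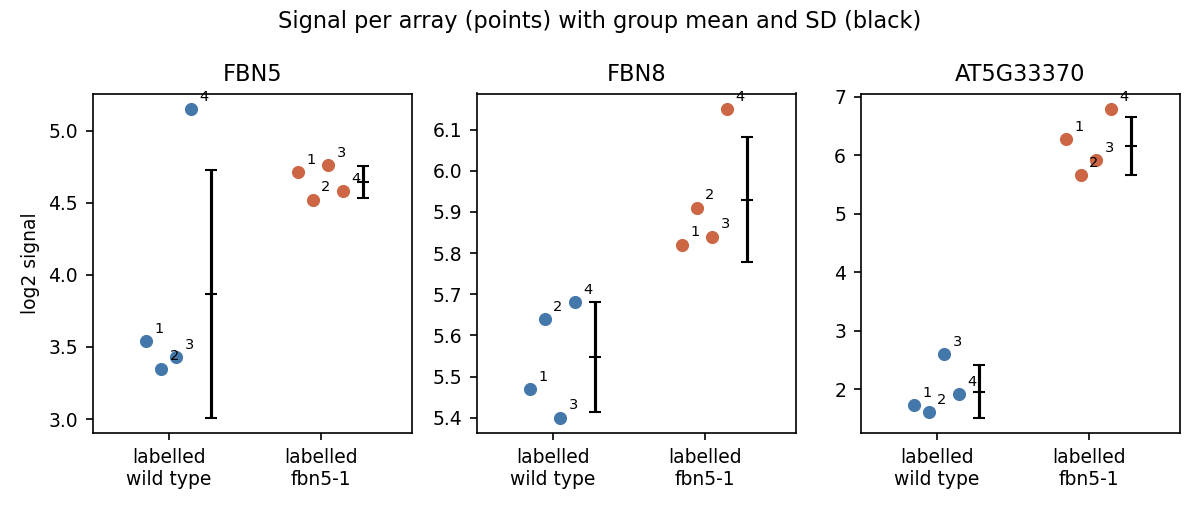
Log2 signal of FBN5, FBN8 and AT5G33370 on each array (vertical axes; points, replicate number beside) by label, with the group mean and SD in black. For FBN5, wild type array 4 (5.15) lies above all 4 arrays labelled fbn5-1, and the other wild type arrays (3.35 to 3.54) lie below them; for AT5G33370 the groups do not overlap.

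Of the other 9 fibrillins with a tested probe set, FBN8 rose in the arrays labelled fbn5-1, by 0.38 on the log2 scale (SE 0.11, adjusted p = 0.0431), and 8 were not called. FBN10 had a difference of 0.31, and FIB (FBN1A), FBN1B, FBN2, FBN3A, FBN3B, PGL34 (FBN7A) and FBN7B had differences between -0.33 and -0.09. The list, FBN5 included, had 1 member higher, 0 lower and 9 not called, and 0 when adjusted over the list alone. It was not called as a list (median -0.12, mean 0.03; adjusted p = 0.774). FBN8's call held without wild type array 4 and ended without each of the other 7 arrays, with an adjusted p of up to 0.108 (without wild type array 3). Of the 18 genes of prenylquinone and tocopherol metabolism, 1 had a tested probe set of its own: NDC1, a plastoglobule quinone reductase, was not called (difference 0.385, SE 0.14, adjusted p = 0.0845).

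Across the array, 2876 of 17147 probe sets (16.8%) changed, 1410 higher and 1466 lower in the arrays labelled fbn5-1. Of these, 1441 name 1 gene, 658 higher and 783 lower. At least 2-fold changes were mostly increases, with 224 probe sets higher and 124 lower; 103 and 59 of these name 1 gene. The 4 arrays of one label all lay above the 4 of the other for 2707 of the 2876, and for 23.58% of all tested probe sets, where chance gives 2.86%. Leaving out an array changed the count, and the influence of that array was not separated from the loss of power with fewer arrays. The count was 1842, 1736 and 1814 without wild type arrays 1, 2 and 3. Without fbn5-1 arrays 1, 2, 3 and 4 it was 1895, 1973, 1809 and 2357. It was 3854 without wild type array 4, with 225 probe sets at least 2-fold higher and 204 lower.

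The 10 genes with the highest increases in the arrays labelled fbn5-1 included AT5G33370. This gene, a GDSL-type esterase/lipase of the cutin synthase family, rose from 1.96 ± 0.45 to 6.16 ± 0.49 (SD, n = 4; adjusted p = 0.000399). AT5G45670, another GDSL-type esterase/lipase, rose by 2.68 (SE 0.19, adjusted p = 0.00049). AT1G10640 and AT1G60590, polygalacturonase-like pectin enzymes, rose by 3.16 (SE 0.36) and 2.29 (SE 0.21), with adjusted p of 0.00211 and 0.000882. AT1G06360, a member of the fatty acid desaturase family, rose from 1.53 ± 0.13 to 4.56 ± 0.73 (adjusted p = 0.00143). The neighbouring genes AT4G22485 and AT4G22490, both of the lipid transfer protein type, were higher by 3.18 (SE 0.90) and 2.798 (SE 0.81), and AT5G48490, of the same type, by 2.27 (SE 0.45). AT4G29030 and AT1G44130, an aspartyl protease, completed the 10 highest with 2.69 (SE 0.44) and 2.26 (SE 0.55). The calls of AT4G22485 and AT4G22490 held without wild type arrays 2 and 4 and ended without each other array, with adjusted p of up to 0.0946 (without fbn5-1 array 2) and 0.1 (without fbn5-1 array 3). On the arrays labelled wild type, AT5G33370 and AT1G06360 lay below the filter value of 2.79, so no size of change is given for them on the deposited scale. With 16 added to the linear signal AT4G22485 had the highest difference of the 10, 2.492, and the others were 2.136 for AT5G33370, 2.02 for AT4G22490, 1.93 for AT5G48490, 1.88 for AT1G10640, 1.74 for AT5G45670, 1.6 for AT4G29030, 1.54 for AT1G60590, 1.52 for AT1G44130 and 1.1 for AT1G06360, so the order depends on signal near the floor. The call of AT1G44130 ended without wild type array 2 and without fbn5-1 arrays 1, 2 and 3, with an adjusted p of up to 0.067 (without fbn5-1 array 3).

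Among the 10 largest decreases, AT1G67865 fell from 10.9 ± 0.12 to 9.34 ± 0.25 (SD, n = 4), by 1.52 on the log2 scale (SE 0.12, adjusted p = 0.000496). SIS, a salt-induced serine-rich protein, was lower by -1.98 (SE 0.27, adjusted p = 0.00316). AGL104, a MADS-box transcription factor known from pollen, fell from 4.59 ± 0.55 to 2.695 ± 0.20, below the filter value (adjusted p = 0.00277). AT2G32160, AT1G64360, AT1G57590 (a pectin acetylesterase) and AT1G51090 were lower by -1.93, -2.06, -1.86 and -1.50, with adjusted p of 0.00214, 0.00903, 0.0143 and 0.016. AT2G35070, AT2G28400 and FAMT (a farnesoic acid methyltransferase) had differences of -2.13 (SE 0.62), -2.02 (SE 0.60) and -1.74 (SE 0.46) and were called with adjusted p of 0.0444, 0.0486 and 0.0333. AT2G35070's call held without fbn5-1 arrays 1 and 4, and AT2G28400's without wild type array 4; without fbn5-1 array 3 their adjusted p were 0.104 and 0.117. FAMT's call ended without wild type arrays 1 and 3 and without fbn5-1 arrays 2, 3 and 4, with an adjusted p of up to 0.0721 (without fbn5-1 array 2). With 16 added to the linear signal, AGL104 had -0.85, and AT2G28400 had -1.24 and lost its call (adjusted p = 0.104).

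Genes of the plastid genome rose as a list in the arrays labelled fbn5-1. Of 63 measured, 22 were higher, 1 lower (psbZ) and 40 not called; 31 were called when adjusted over the list alone. The median difference was 0.11 (camera adjusted p = 0.000706 over the 10 lists fixed beforehand; adjusted p = 0.56 with an estimated correlation). Among members called over all probe sets, the largest increases were in rps19, a ribosomal protein (0.74, SE 0.07, adjusted p = 0.000857), psbM, a small photosystem II subunit (0.61, SE 0.13, adjusted p = 0.0154), rpoC2, an RNA polymerase subunit (0.52, SE 0.08, adjusted p = 0.00476), and ndhH, of the NADH dehydrogenase-like complex (0.49, SE 0.08, adjusted p = 0.0064). The gene rpl33, another ribosomal protein, chosen after its values were seen, had a difference of 0.58 and was called over the list alone only (SE 0.19, adjusted p = 0.0681 over all probe sets). The list's call ended with quantile normalization, which left a median of 0.015, 14 members higher and 5 lower (adjusted p = 0.439, the highest of 20 alternatives). The 22 higher members were 11 without wild type array 1 or 3 or fbn5-1 array 1, 12 without fbn5-1 array 3, and 13 without wild type array 2 or fbn5-1 array 2. They were 8 without an intensity trend, where psbZ lost its call, and 10 with the replicate number as a block.

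Within the plastid genome, calls were counted by function. Of 13 genes for ribosomal proteins, 7 rose and 0 fell (median 0.21). Of 4 for RNA polymerase, rpoA, rpoB and rpoC2 rose (median 0.32). Of 10 for the NADH dehydrogenase-like complex, 5 rose and 0 fell (median 0.13). Of 7 for cytochrome b6f and cytochrome assembly 2 rose (median 0.11), and of 5 other genes 2 (median 0.17). Of 4 for ATP synthase, 0 were called (median -0.01). Of 20 photosystem genes, 13 for photosystem II and 7 for photosystem I, 3 rose (psbM, psbI and ycf4) and psbZ fell; their medians were negative with quantile normalization, at -0.06 and -0.08. The calls of psbI and ycf4 held without wild type array 4, and that of psbI without fbn5-1 array 4; both ended without each other array, with adjusted p of up to 0.0834 (psbI, without wild type array 2) and 0.0848 (ycf4, without wild type array 3). Without an intensity trend, of these 20 genes 1 was higher and 0 lower. The mean log2 signal on the arrays labelled wild type was 11.7 for photosystem I and 11.3 for photosystem II genes. Compression of signals near the top of the range was not tested, so the functions were not compared with each other. The ribosomal and RNA polymerase lists, drawn up once the symbols on the array were known, had camera adjusted p of 0.00088 and 0.0324 over 39 lists (adjusted p = 0.584 and 0.619 with an estimated correlation). The ribosomal list was called in all 20 alternatives, with 4 members higher without wild type array 1 or 2, without an intensity trend and with the replicate block. The RNA polymerase list lost its call without wild type array 3 (adjusted p = 0.0665), without fbn5-1 arrays 1, 2 and 3 (0.0542, 0.0575 and 0.0584), with quantile normalization (0.0588) and with the full series table (0.0512). The calls of rpoA and rpoB ended without wild type arrays 1 and 3 and without fbn5-1 arrays 1, 2 and 3, with adjusted p of up to 0.0776 and 0.0683.

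Of 6 tested nuclear genes of photosystem II and its antenna, 0 were called over all probe sets and 3 when adjusted over the list alone, with a median of -0.06 (camera adjusted p = 0.774); PSBW was called without wild type array 4 (-0.22, SE 0.05, adjusted p = 0.0153). PSAE-1, a photosystem I subunit, was lower by -0.17 (SE 0.05, adjusted p = 0.0392), and its call held only without wild type array 4 or fbn5-1 array 4, with an adjusted p of up to 0.107 (without wild type array 2). The Calvin-Benson cycle list (PRK, RCA and SBPASE) had 0 of 3 members called, and 0 when adjusted over the list alone (median -0.03, mean 0.045; adjusted p = 0.774); SBPASE was called without wild type array 1 (0.30, SE 0.07, adjusted p = 0.0366). In chlorophyll biosynthesis, GSA1, a glutamate-1-semialdehyde aminotransferase, rose by 0.74 (SE 0.07, adjusted p = 0.00101) and CHLP, the geranylgeranyl reductase that makes phytyl chains, by 0.37 (SE 0.08, adjusted p = 0.0142). CHLM, HEMA2 and PORB were not called, except CHLM without wild type array 4 (0.30, SE 0.08, adjusted p = 0.028). With 2 of 5 higher and 3 when adjusted over the list alone, this list had an adjusted p of 0.0616 (adjusted p = 0.449 with an estimated correlation), and of 0.0282 without wild type array 4 (0.0139 to 0.114 over 20 alternatives).

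The chloroplast ascorbate peroxidases SAPX and TAPX, which remove hydrogen peroxide, rose by 0.84 (SE 0.12, adjusted p = 0.00391) and 0.36 (SE 0.08, adjusted p = 0.0161) in the arrays labelled fbn5-1. They were 2 of the 3 tested members of the oxidative and high-light stress list, and were also those called when adjusted over the list alone. STZ, the third, had a difference of 0.57 with an SE of 1.12, and of 1.91 without wild type array 4 (SE 0.30, adjusted p = 0.00324), where all 3 members were higher. The list had an adjusted p of 0.0616 (adjusted p = 0.449 with an estimated correlation), and of 0.00701 without wild type array 4 (0.00701 to 0.114 over 20 alternatives), on which STZ was at 9.85 against a mean of 4.48 on the other wild type arrays.

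Of 4 cold- and dehydration-induced genes, 2 fell in the arrays labelled fbn5-1. KIN2 was lower by -1.26 (SE 0.32, adjusted p = 0.0286) and COR47 by -1.12 (SE 0.31, adjusted p = 0.0391), while COR15A and COR15B were not called. The list, with 2 of 4 members lower, also when adjusted over the list alone, had an adjusted p of 0.0616 (adjusted p = 0.56 with an estimated correlation). It was 0.182 without wild type array 4, and passed the threshold without wild type array 2 (0.0306) and fbn5-1 array 4 (0.047), without a filter (0.0471) and with the replicate number as a block (0.00142, 3 members lower), with a range of 0.00142 to 0.188 over 20 alternatives. KIN2's call ended without wild type arrays 1 and 3 and without fbn5-1 arrays 1, 2 and 3, with an adjusted p of up to 0.0707 (without fbn5-1 array 2). COR47's held only without wild type array 4 or fbn5-1 array 4, with an adjusted p of up to 0.0951 (without fbn5-1 array 3). On wild type array 4 both genes were higher, by 1.05 and 1.18, than the mean of the other wild type arrays.

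Genes of cell division and DNA replication were higher in the arrays labelled fbn5-1. Of 18 in a list drawn up once the symbols on the array were known, 12 rose, 0 fell and 6 were not called; 13 were called when adjusted over the list alone. The median difference was 0.74 (camera adjusted p = 2.18e-07 over 39 lists at the preset correlation of 0.01). The estimated correlation was 0.507, and with it the camera adjusted p was 0.584. TOPII, a DNA topoisomerase, rose by 1.71 (SE 0.18, adjusted p = 0.00145), BUBR1, of the spindle checkpoint, by 1.54 (SE 0.29, adjusted p = 0.00928), ICU2, a DNA polymerase subunit, by 1.28 (SE 0.26, adjusted p = 0.0134), and AUR2, an Aurora kinase, by 1.202 (SE 0.24, adjusted p = 0.0115). AUR2 and AUR1 (0.97, SE 0.23, adjusted p = 0.0233) were the 2 tested members of the cell cycle list fixed beforehand. AUR1 lost its call without wild type array 1 and without fbn5-1 arrays 1, 3 and 4 (adjusted p of up to 0.0645, without fbn5-1 array 3). Called members were mostly dim on the arrays labelled wild type, with means from 2.58 (HTB2) to 4.87 (FBL17), against a filter value of 2.79. TOPII, BUBR1, ICU2 and AUR2 had means of 3.2, 2.9, 3.07 and 3.08 there, so the sizes of these changes depend on signal near the floor. With the 60th percentile filter, which takes out dimmer probe sets, the division list had an adjusted p of 0.0509, with a median of 0.34 and 2 members called. With 16 added to the linear signal its median was 0.32 with 12 members called. Differences of TOPII, BUBR1, ICU2, AUR2 and AUR1 were then 0.87, 0.71, 0.57, 0.55 and 0.51, all called. The adjusted p of the list lay between 1.17e-09 and 0.0509 over 20 alternatives.

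Several autophagy genes of the ubiquitin-like ATG8 family fell in the arrays labelled fbn5-1. Of 10 ATG8 and ATG3 genes in another list of that kind, 5 fell, 0 rose and 5 were not called; 6 were called when adjusted over the list alone (median -0.51; camera adjusted p = 0.00088; adjusted p = 0.584 with an estimated correlation). ATG8F and ATG8C fell by 0.85 (SE 0.10, adjusted p = 0.00239) and by 0.60 (SE 0.10, adjusted p = 0.00551). ATG8E and ATG8B were lower by -0.70 and -0.59. Both lost their calls without wild type arrays 2 and 3 and fbn5-1 arrays 1, 2 and 3, and ATG8B also without wild type array 1, with adjusted p of up to 0.0821 (without fbn5-1 array 1) and 0.0872 (without fbn5-1 array 3). In each of the 5 fits that ended both calls, 3 members were lower, and the list itself stayed called in all 20 alternatives, with a median of -0.32 with 16 added.

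**Figure D2:**
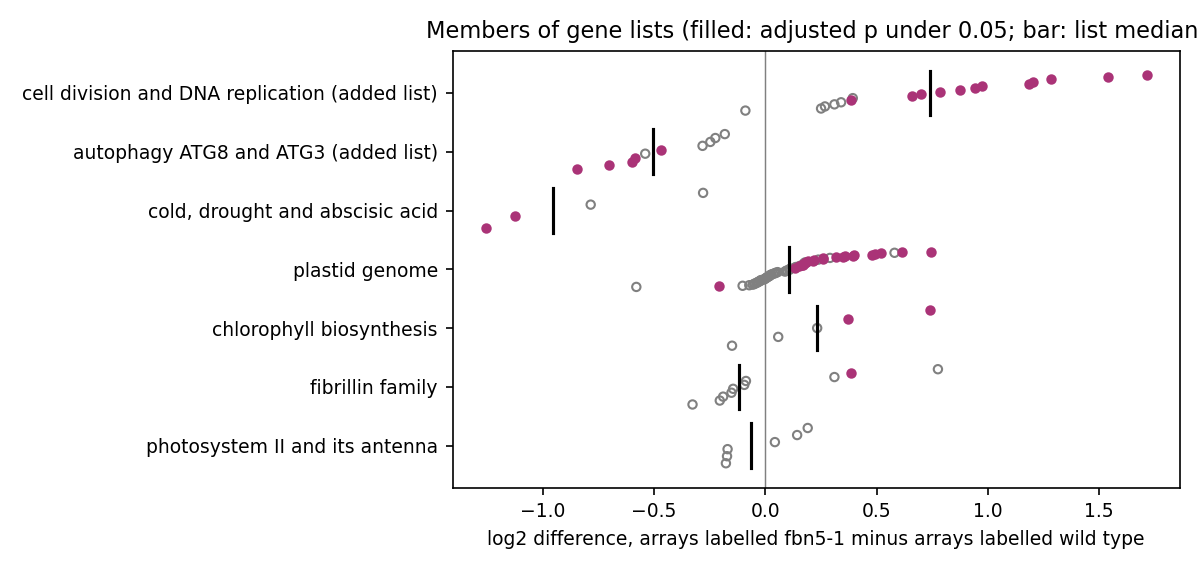
Log2 difference of each list member, arrays labelled fbn5-1 minus arrays labelled wild type (horizontal axis; points, filled where the adjusted p is under 0.05), for 7 lists, with each list's median as a bar. Most of the division list (median 0.74, added) lies to the right of 0, with CKS at -0.09, and the autophagy list (median -0.51, added) to the left, while the plastid genome (median 0.11) is close to 0; quantile normalization took the plastid genome's median to 0.015.

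Several markers from short lists stood out singly. SPCH, which starts the stomatal lineage, was called higher (adjusted p = 0.0432). Its mean was 2.53 ± 0.25 on arrays labelled wild type and 4.24 ± 1.16 on those labelled fbn5-1 (SD, n = 4). The wild type mean lay below the filter value of 2.79, so no size of change is given on the deposited scale. FMA, which acts at the end of that lineage, had a difference of -0.19 (SE 0.15, adjusted p = 0.411). TRY, a trichome regulator, rose by 0.93 (SE 0.23, adjusted p = 0.0282), UGT74C1, of glucosinolate synthesis, by 0.52 (SE 0.12, adjusted p = 0.02) and the mitochondrial genes ccb382 and nad7 by 1.02 (SE 0.20, adjusted p = 0.0119) and 0.33 (SE 0.09, adjusted p = 0.0402). SWEET11, a sucrose exporter, fell by 0.62 (SE 0.08, adjusted p = 0.00273), and GI, of the circadian clock, by 0.495 (SE 0.12, adjusted p = 0.0236). With 16 added to the linear signal the difference of SPCH was 0.76 (adjusted p = 0.0692). SPCH's call held only without wild type array 4 or fbn5-1 array 2 (adjusted p of up to 0.105, without fbn5-1 array 1), and that of nad7 only without wild type array 4 or fbn5-1 array 4 (up to 0.0958, without fbn5-1 array 3). TRY's call ended without wild type array 2 and fbn5-1 arrays 1, 2 and 3 (up to 0.0776), GI's without fbn5-1 arrays 1 and 2 (up to 0.0608), and that of UGT74C1 without wild type array 3 (0.0548).

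As lists, the mitochondrial genome (2 of 15 higher, 0 lower; 3 when adjusted over the list alone), sugar and starch (1 of 3 lower; 1 over the list alone), and flavonoid and anthocyanin genes (0 of 4; 0 over the list alone) were not called, with adjusted p of 0.396, 0.396 and 0.946. In the mitochondrial genome, atp1, nad2 and nad9 were lower without wild type array 4, by -0.38, -0.31 and -0.25 (adjusted p = 0.0171, 0.00546 and 0.00675). The flavonoid list had a median of -0.045 and a mean of 0.04. Of the 10 lists fixed beforehand, 1 was called with the preset correlation, 0 with an estimated one and 3 by fry (plastid genome, chlorophyll biosynthesis, and oxidative and high-light stress; fry adjusted p = 0.017, 0.00841 and 0.0463). Of all 39 lists, 6 were called with the preset correlation, 0 with an estimated one and 12 by fry. Among the 35 ways to split the 8 arrays into 4 and 4, 21 called at least 1 of the fixed lists and 6 called at least 6 of all lists (highest of the other splits 5 and 9).

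Wild type array 4 stood apart from the other 7. Its correlation across probe sets with another array was at most 0.964, where the lowest among the other 7 was 0.974. Against the mean of wild type arrays 1 to 3, it was over 2-fold higher for 631 probe sets and over 2-fold lower for 499. The wound- and jasmonate-induced transcription factor ORA47 was at 7.57 against 2.09 to 2.29 on the other wild type arrays, and the stress-induced zinc finger STZ at 9.85 against 4.17 to 4.95. PYK10, a beta-glucosidase abundant in roots and hypocotyls, was at 6.84 against 9.23 to 9.70, and DFR, of anthocyanin synthesis, at 4.21 against 6.15 to 6.78. These genes were chosen after their values were seen. The deposited log2 medians were 3.44 on average in the arrays labelled wild type and 3.48 in those labelled fbn5-1 (exact permutation p = 0.0286, 0.114 after adjustment over 4 measures). Medians of the 9825 probe sets found in the series table alone did not separate the groups (exact permutation p = 0.257). Neither the spread of relative log expression nor the correlation with the own group did so (exact permutation p = 0.657 and 0.4).

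**Figure D3:**
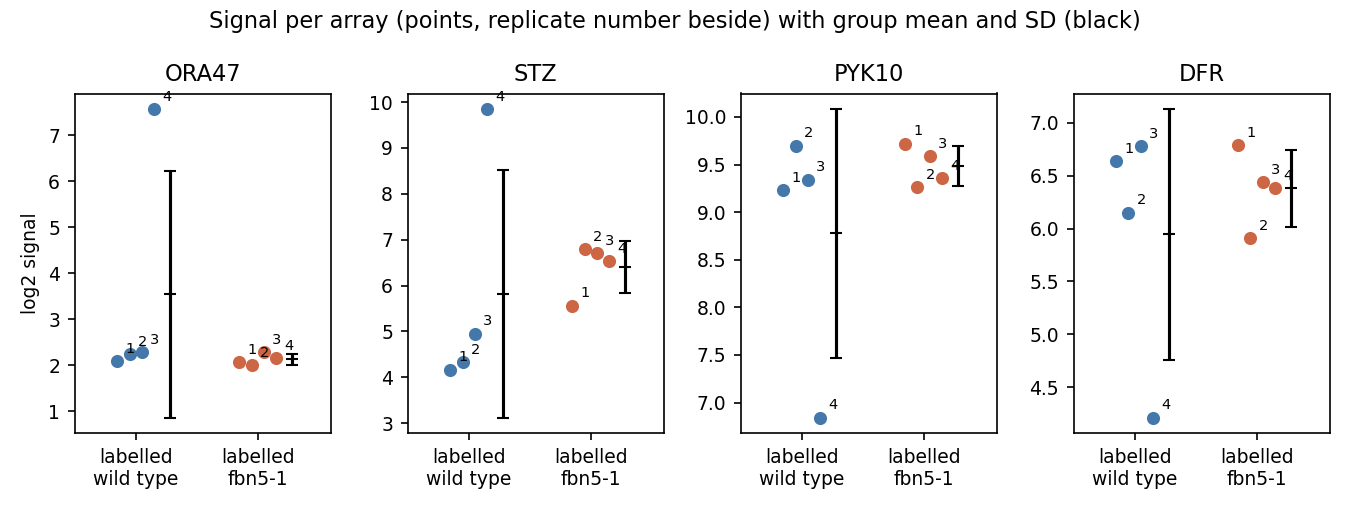
Log2 signal of ORA47, STZ, PYK10 and DFR on each array (vertical axes; points, replicate number beside) by label, with the group mean and SD in black. In each gene wild type array 4 lies apart from the other 7 arrays: at 7.57 in ORA47 and 9.85 in STZ above them, at 6.84 in PYK10 and 4.21 in DFR below them.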

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

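All tests here were chosen after the results were seen, except that of wild type array 4 after quantile normalization and those of other splits for the number of lists called. In 66 named genes with 2 groups of 4 arrays each, 15 of 132 groups (11.4%) held 1 array far from the other 3, where chance gives 5%. Over all 17147 tested probe sets the share was 9.28% in the arrays labelled wild type and 5.13% in those labelled fbn5-1. Part of the excess was thus not particular to the named genes. Wild type array 4 was the array apart in 7 of the 15.

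Wild type array 4 was far from the other wild type arrays in its correlation with the mean of its group (0.935, against 0.985 for the mean of the others) and in the spread of its relative log expression (interquartile range 0.375, against 0.258). Named genes in which it stood apart were FBN5 (5.15, against a mean of 3.44 on the other 3), FBN3B (6.2, against 5.84), AT2G28400 (7.57, against 4.73), GI (8.06, against 7.68), COR47 (7.64, against 6.46), TOPII (2.85, against 3.31) and ICU2 (2.33, against 3.32). So did the means of the oxidative and high-light stress list (7.89, against 6.19) and of the division list (3.56, against 3.93).

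For this array, an exchange with an array labelled fbn5-1 cannot be judged from FBN5. Of the 4 arrays labelled fbn5-1, 0 had FBN5 as low as wild type arrays 1 to 3. That decides nothing, since FBN5's level may check nothing about the labels. Over probe sets called with each array held out, those labelled fbn5-1 had median positions of 0.82 to 0.948 (0 wild type, 1 fbn5-1). These positions argue against an exchange. A single wrong label on a sample of the fbn5-1 line is argued against too, although FBN5 itself went with that label: over the 3854 probe sets called without this array, its median position was 0.221 between wild type arrays 1 to 3 (0) and the arrays labelled fbn5-1 (1), where the other arrays, each held out, departed from their own label by at most 0.18; 66.7% of these probe sets lay nearer wild type, against 90.3% to 92.8% for the other wild type arrays and 10.4% to 21.8% for the arrays labelled fbn5-1. Scaling is argued against: after quantile normalization it still had 1174 outlying probe sets, where the highest of the other arrays had 282. Noise independent between genes would put about 5% of lists outside the central 95% of random lists matched on level, and 26.3% (10 of 38 lists without shared members) lay outside. An exchange with a sample outside these 8 stays open, and the design gives no group for this array, so no biological explanation was tested.

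FBN5 had a higher signal on the arrays labelled fbn5-1 than on 3 of the 4 arrays labelled wild type, in a line meant to disrupt it. A change of the whole region is argued against: of the 10 nearest genes with a probe set of their own, those past the filter had a median difference of -0.0325 (SD 0.276) without wild type array 4, where FBN5 had 1.203. The nearest of them after FBN5, AT5G09840, rose by 0.58 in that fit (SE 0.16, adjusted p = 0.0284), so a change of FBN5 and this gene alone stays open; AT5G09720, AT5G09780, AT5G09800 and AT5G09876 lay below the filter and exclude nothing. Labels exchanged between the groups as a whole cannot be told apart from transcription of the measured part of the gene in the mutant, because 3 wild type arrays below every array labelled fbn5-1 are what both would give, and the place of the probes relative to the insertion is not known.

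The division list's call ended with an estimated correlation (camera adjusted p = 0.584) and with the 60th percentile filter (0.0509). At the preset correlation, the camera adjusted p was at most 4.06e-07 under the 3 other scalings, but that p rests on the preset. The list's median lay between 0.32 and 0.82 over 20 alternatives, these scalings included, so the direction of its increase was not set by the choice among them. Wild type array 4 alone did not set the increase, since without it the list's median was 0.74 (0.7425). A higher share of young leaf tissue could also raise it; the leaf polarity and development list had a median of 0.14 (0.139, SD of its members 0.183), which decides nothing. Of its members with the highest signal, YAB3 rose from 6.17 to 6.5 (adjusted p = 0.0196), AN (5.76 and 5.92) and YAB5 (5.7 and 5.525) were not called, YAB2 and PHV had differences of -0.14 and -0.105, and with the 60th percentile filter the median was -0.105. SPCH (adjusted p = 0.0432) and TRY (0.93, adjusted p = 0.0282), which act in the epidermis of young leaves, rose with the division list. With 16 added to the linear signal, SPCH had a difference of 0.76 and lost its call (adjusted p = 0.0692). Over the alternatives, SPCH's call ended in 12 of 18, quantile normalization among them, and TRY's in 5 of 19, so neither gene decides the question. Genotype stays open as well.

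Other arrays stood apart in single genes. Of the 132 groups of named genes, 8 were flagged for them, where chance gives 5%, so no excess was shown for these arrays. They were fbn5-1 array 2 in FBN7B (4.67) and AUR1 (3.94), fbn5-1 array 3 in AT2G28400 (2.96), TRY (6.67) and TAAC (5.38), fbn5-1 array 4 in CHLP (9.86) and ATG8B (5.19), and wild type array 3 in ATG8B (5.79).

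Of the 35 ways to split the 8 arrays into 4 and 4, 1, the real one, gave as many changed probe sets as the 2876 found, and the highest of the others gave 1; for at least 2-fold changes the numbers were 1 split, 348 and 1. No other split reached either count, and 35 splits allow no share below 1 of 35. The splits cannot exclude differences between plants or cultures, as the replicates may be technical. A chance split cannot be excluded for the number of gene lists called. At least 1 of the fixed lists was called by 21 of the 35 splits (highest other 5). At least 6 of all 39 were called by 6 of the 35 (highest other 9).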

How the results depend on the processing

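Counting identical probe sets once and testing the added lists were chosen after seeing the data. The count of 2876 changed probe sets lay between 2430 and 3085 under the other scalings, 16 added, both filters, both variance models and the full series table, was 2867 with identical probe sets counted once, and was 4450 with array weights, of which 2863 were shared. It lay between 1736 and 3854 with 1 array left out. The 348 at least 2-fold changes were 119 with 16 added before log2, which compresses changes of dim probe sets, and between 257 and 501 otherwise. The FBN5 difference was 0.6025 to 1.203 with 1 array left out and passed the threshold only without wild type array 4 and with array weights (1.14); it stayed positive in all alternatives.

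Where 1 fixed list was called, the number was 0 with quantile normalization and with an estimated correlation, 4 without a filter, 2 with the 60th percentile filter, 3 without an intensity trend, with a robust trend, with array weights and by fry, 6 of 39 with the added lists, and 1 to 3 with 1 array left out; the cause was not tested. Of 57 called named genes, 38 to 57 kept their call. With 1 array left out, FBN7B lay between -0.1667 and 0.05167, reversed without fbn5-1 replicate 2, and FBN3B between -0.1675 and 0.005833, reversed without fbn5-1 replicate 1 and, at 0.003333, without wild type replicate 4; neither was called. Signal over background could not be judged without detection calls.

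The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at 0.157, -0.187, -0.0367 and 0.00185, and 1 of the 4 wild type arrays correlated best with its own number. With the replicate block, 1731 probe sets changed, 305 at least 2-fold, and 2 fixed lists were called.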

Other observations

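Tests and genes named here were chosen after the results were seen, except that the lists were drawn up before any gene was compared between groups. Other groups drawn from the symbols on the array held called members without a camera call of the list. In the unfolded protein response list, DER2.2 and DER2.1, which act in degradation of endoplasmic reticulum proteins, fell by 0.68 (SE 0.08, adjusted p = 0.00239) and by 0.69 (SE 0.15, adjusted p = 0.016) in the arrays labelled fbn5-1. CRT1b, a calreticulin, rose by 0.41 (SE 0.11, adjusted p = 0.0338). Of the 12 list members, 1 was higher and 3 were lower. Camera did not call the list (adjusted p = 0.146, and 0.584 with an estimated correlation), but fry did (fry adjusted p = 0.00396 over 39 lists). SWEET2, a sugar transporter of the vacuole, rose by 1.26 (SE 0.19, adjusted p = 0.00392), while SWEET11 of the same list fell. Of 18 expansins and xyloglucan endotransglucosylases, which loosen cell walls, 3 rose and 0 fell, led by EXPB1 (1.38, SE 0.24, adjusted p = 0.00658), and the list was not called (adjusted p = 0.441).

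In a list of photosynthetic complex assembly and plastid RNA factors, 7 of 32 members rose and 3 fell in the arrays labelled fbn5-1 (median 0.24; camera adjusted p = 0.00556; adjusted p = 0.619 with an estimated correlation). TAAC, a thylakoid ATP/ADP carrier, rose by 0.88 (SE 0.13, adjusted p = 0.00379) and CRR21 by 0.74 (SE 0.18, adjusted p = 0.0252). CRR41, needed for the NADH dehydrogenase-like complex, rose by 0.69 (SE 0.13, adjusted p = 0.00875), and LIL3:1, of chlorophyll synthesis, by 0.58 (SE 0.10, adjusted p = 0.00584). CRR21's call ended without wild type array 3 (adjusted p = 0.0681), without fbn5-1 arrays 1, 3 and 4, and with the replicate block. TRXF2, SRX and PIFI fell. With 16 added to the linear signal, CRR41 had 0.32.

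The 4 array means of one label all lay above the 4 of the other in 12 of the 39 lists. Chance gives 1.11 lists (2.86%) if lists were independent, and the highest of the other splits gave 3. The lists are not independent: the 12 include the plastid genome and also its ribosomal, RNA polymerase, NADH dehydrogenase-like, cytochrome and remaining genes as lists. Of all tested probe sets, 23.58% separated the groups in this way, so no excess particular to lists was shown.

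On wild type array 4 alone, AT4G29780 was at 9.08 against a mean of 2.99 on the other wild type arrays, CML38, a calmodulin-like protein, at 6.54 against 1.31 to 1.91, and BZIP60, of the unfolded protein response, at 7.34 against 4.71 to 4.89. In the same array TBL36 was at 2.75 against 6.85 and bZIP58 at 1.32 against 5.86. STZ was at 5.56 to 6.79 on the arrays labelled fbn5-1, between wild type array 4 and the other wild type arrays. On this array, U-box ubiquitin ligases (median 1.46 above the other wild type arrays; PUB22, PUB23 and PUB24) and cold and dehydration genes (1.08) were high, and flavonoid genes (-1.02) and beta-glucosidases (-0.77) low.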
